A study of Arabidopsis thaliana with 36 samples.

How the data were processed

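Poly(A) RNA of whole rosettes of 4-week-old Arabidopsis Col-0 plants grown in short days was sequenced from directional libraries, 3 replicates for each of 12 groups. The groups were mock, 10 cGy or 100 cGy of gamma rays at 1, 3, 24 or 72 h after exposure, 36 libraries in all. Groups, doses, times and replicate numbers were read from the sample labels, and 0 data columns were left unused. Tools named for the upstream steps are Trimmomatic 0.32, STAR 2.5.2b and RSEM 1.2.28 with the genome build TAIR10, per the submitters' processing notes. The notes give no role, order, filter or annotation for them.

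The deposited main table holds CPM for 33977 genes, and each library sums to 1e6. A second deposited table holds the natural log of CPM + 1, made by the authors: it differed from the log of the first table by at most 4.1e-09. Between 88.8% and 90.6% of the values above 0 in a library were whole multiples of its smallest step (tolerance 0.02). The rest were not, so whole reads were recovered for most values but not for all, and count-based tests were not used. The step gave a depth of 22.1 to 36.7 per library in units of 1e6 and a floor of 3 counts at 0.0818 to 0.136 CPM, and such floors cover counting error only. Locus tags of 32548 genes matched the TAIR10.1 reference, which was used for names only, without coordinates. Among the tested genes 18802 matched, 73 did not and 64 were organelle genes. The Arabidopsis locus AT4G02390 is called PARP2 here and AT2G31320 PARP1, since the numbering of these genes differs between sources. Reads shared by near-identical gene copies are not resolved by such values.

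Genes with CPM of at least 1 in at least 3 of the 36 libraries were kept, which left 18875. Values were taken as log2(CPM + 0.5), which makes the fold changes of weakly expressed genes smaller than those of their CPM means. Linear models with 1 mean per group were fitted to all 36 libraries with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with an intensity trend in the moderated variance. The p-values were adjusted by Benjamini and Hochberg within each contrast, with calls at 0.05. The contrasts were each dose against mock at each time (8), 100 cGy against 10 cGy at each time (4), the change of each dose's effect between successive times, and mock plants at 3, 24 and 72 h against 1 h. Overlap of calls between doses was set against the number for independent lists, and the correlation, covariance and signs of the fold changes against 100 simulated draws of unchanged groups. In each draw all libraries of a time, mock included, were the mock mean plus residuals of libraries of the other times. Both doses shared the simulated mock libraries. Quality tables and figures were made with python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

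Gene lists were fixed before the data were examined: DNA damage response, DNA repair and damage signalling, ethylene synthesis and signalling, ethylene response factors with ethylene-responsive defence, cold response and touch with wound and early stress. Further lists cover jasmonate, salicylate with immunity, antioxidant, abscisate with dehydration, heat shock, circadian clock, S phase, G2 with mitosis, DNA methylation and silencing and photosynthesis. The rest cover flavonoids, iron status, senescence with sugar starvation, root markers and flowering markers. These 21 lists hold 364 members, of which 332 were tested. The symbols of 13 members were absent from the reference and 1 locus (ACO3) was contradicted by it. Lists with enough measured members (19) were tested with camera in limma at a preset correlation of 0.01, with adjustment over all 152 tests of the contrasts with mock, and again with an estimated correlation and with fry. Root and flowering markers had 1 measured gene each and were not tested as lists. Counts "adjusted over the list alone" adjust p-values within the list.

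Named genes followed a rule written before the data were examined. In each contrast with mock it takes the 6 largest rises and the 6 largest falls among called genes whose 3 irradiated libraries all lie above or all below the 3 mock libraries (all called genes where 10 or fewer were called). It adds up to 4 called members of each list with the smallest p, and fixed sentinel genes for DNA damage (BRCA1, PARP2, GMI1, TSO2, SMR5, SMR7, CYCB1;1, XRI1 and SOG1) and ethylene (ACS6, EIN3, EBF2, ERF1, ERF5). Some genes that the rule takes are not reported here. Only a part of the genes it takes is printed, with preference for calls that held without any 1 library. The numbers that held were 55 of 76 (10 cGy, 1 h), 5 of 29 (3 h), 7 of 24 (24 h) and 11 of 33 (72 h). For 100 cGy they were 48 of 63, 21 of 57, 1 of 13 and 1 of 18. Lists of dark-induced and light-induced genes and 26 groups of genes by product name were made after the data were seen.

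Pairs of replicates within a group had Pearson correlations of 0.979 to 0.994. The deviations of same-numbered libraries from their group means were checked for pairing in 12 comparisons of groups within a time. Only for 100 cGy against mock at 24 h were all 3 correlations above 0.1 (0.248 to 0.341), each library being closest to its own number, so a fit with the number as a block is printed beside that count alone. The procedure was tested on simulated data built on the 100 cGy 1 h design with 18875 genes: 45 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold were recovered. There were 9 false calls in that comparison and 0 in 7 comparisons without change, and 0 of 20 lists of unchanged genes were called. The simulated genes varied independently and the lists were drawn at random. The result for lists therefore does not cover lists whose genes vary together.

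Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter and a stricter filter (mean CPM of at least 5) and rescaling of libraries by median ratios. Others were the authors' log table, fits to the libraries of 1 time only, a replicate block, array weights and leaving out each library in turn. The same settings for overlaps and for differences between times, and the fit without replicates 2 and 3 of the 100 cGy 3 h group, were added after the data were seen. Group labels were also exchanged within times, in all 10 splits of 6 libraries or in 100 drawn splits of 12.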

Results

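Messenger RNA was measured in whole rosettes of Arabidopsis thaliana Col-0 plants that had been exposed to gamma rays from a 137Cs source, or of mock plants. How mock plants were handled is not given in the labels. The dose was 10 cGy or 100 cGy, and rosettes were harvested 1, 3, 24 and 72 h after exposure. The 3 treatments and 4 times made 12 groups of 3 libraries each, 36 libraries in all. The depth of a library, recovered from the step between its CPM values, ran from 22.1 to 36.7 in units of 1e6, with a median of 31.3. A floor of 3 counts thus stood for 0.0818 to 0.136 CPM. Between 17505 and 18145 genes per library reached 1 CPM. Of 33977 genes in the table, 18875 passed the filter and were tested. All values below have n = 3 libraries per group, fold changes are log2 differences of group means of log2(CPM + 0.5) with their standard error (SE), and adjusted p-values come from limma. The labels do not say whether replicates were separate plants or separate exposures, so the p-values measure only the spread between these libraries. That spread is estimated per gene over all 12 groups together. With only the libraries of the time in the fit, counts against mock at 3, 24 and 72 h were far lower, as given under processing below.

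At 1 h after 10 cGy, the lower dose, the comparison with mock asked how rosettes respond to little radiation. The largest rises were in AT4G21870 (4.49, SE 0.24, adjusted p = 1.34e-13) and AT1G72416 (4.48, SE 0.18, adjusted p = 1.36e-16). They were followed by the ethylene response factor family gene AT5G61590 (4.01, SE 0.24, adjusted p = 1.59e-12) and the abscisate receptor gene PYL6 (AT2G40330; 3.40, SE 0.28, adjusted p = 4.25e-10). The largest falls included the xyloglucan-modifying enzyme gene XTH31, which fell by 2.01 (SE 0.22, adjusted p = 4.22e-08) and the beta-expansin gene EXPB1 by 1.65 (SE 0.13, adjusted p = 1.26e-10). Of 21 measured genes for ethylene synthesis and signalling, 9 rose and 1 fell, and the same 9 and 1 passed when adjusted over the list alone. Among them were the F-box gene EBF2, whose product removes the ethylene transcription factor EIN3 (0.53, SE 0.07, adjusted p = 3.57e-06), and the kinase gene CTR1, which holds the pathway off (0.62, SE 0.08, adjusted p = 5.36e-07). The receptor gene ERS1 (0.46) and the ACC synthase gene ACS4 (1.17, SE 0.21, adjusted p = 0.000103) rose too. The list as a whole lay above other genes (camera adjusted p = 0.00314), and adjusted p = 0.202 with an estimated correlation. Of 21 ethylene response factors and ethylene-responsive defence genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone). HRE1, a low-oxygen response factor, rose by 1.47 (SE 0.13, adjusted p = 2.56e-09), ORA59, a regulator of jasmonate and ethylene defence genes, by 1.63, ERF2 by 2.38 and ERF5 by 1.01. That list had a camera adjusted p = 0.00178, and adjusted p = 0.455 with an estimated correlation.

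The touch, wound and early stress genes also rose at 1 h after 10 cGy: 11 of 20 passed and none fell (13 adjusted over the list alone). Among them were WRKY18, a transcription factor of defence (2.40, SE 0.33, adjusted p = 3.15e-06), the deadenylase gene CAF1A (1.49, SE 0.22, adjusted p = 9.72e-06) and the touch gene TCH3 (1.12). Their camera adjusted p = 1.8e-05 became adjusted p = 0.542 with an estimated correlation. Of 23 jasmonate genes 6 rose (9 adjusted over the list alone), including CYP94C1, which inactivates the hormone (2.26, SE 0.46, adjusted p = 0.000524), and AOC3, an enzyme of its synthesis (2.16). The jasmonate list had an adjusted p = 0.0094, an adjusted p = 0.79 with an estimated correlation, and an adjusted p = 0.101 without 10 cGy replicate 2. Genes of S phase and DNA replication fell, 9 of 13 (10 adjusted over the list alone). Examples are the ribonucleotide reductase gene RNR2A (-0.35, SE 0.06, adjusted p = 8.09e-05) and the helicase genes MCM2 (-0.38) and MCM7 (-0.42). The list had an adjusted p = 0.000119, and adjusted p = 0.455 with an estimated correlation. Of 24 genes of DNA repair and damage signalling, 8 fell and none rose (8 fell and 1 rose adjusted over the list alone). Among them was ATRIP, the partner of the checkpoint kinase ATR (-0.64, SE 0.07, adjusted p = 1.99e-07). That list's adjusted p = 0.0215 became adjusted p = 0.542 with an estimated correlation and 0.0531 without 10 cGy replicate 3. Of 19 genes of DNA methylation and silencing 3 fell, by both counts, including the maintenance methyltransferase gene MET1 (-0.42, SE 0.08, adjusted p = 0.000342) and AGO4 (-0.31), an Argonaute of RNA-directed methylation. The methylation list's adjusted p = 0.0268 became 0.1 without 10 cGy replicate 3 and adjusted p = 0.542 with an estimated correlation. The clock genes went both ways, 5 up and 5 down of 22 (6 and 5 adjusted over the list alone; adjusted p = 0.875). The clock-controlled repressor gene CDF1 stood at -1.15 (SE 0.07, adjusted p = 2.68e-12) and the Myb gene RVE1 at 0.86.

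The 22 measured DNA damage response genes did not move together 1 h after 10 cGy, with 3 up and 4 down by both counts and an adjusted p = 0.609 for the list. The break-sensing polymerase gene PARP2 (AT4G02390) stood at 0.17 (adjusted p = 0.333), BRCA1 at -0.25, the ribonucleotide reductase gene TSO2 at -0.15, the cell cycle inhibitor gene SMR7 at -0.08 and the cyclin gene CYCB1;1 at -0.31, none past the test. XRI1, an X-ray inducible repair gene, rose by 0.35 (adjusted p = 0.00592, but 0.0537 without 10 cGy replicate 3). GMI1, a recombination gene, fell by 0.58 (adjusted p = 0.00971, but 0.0757 without 10 cGy replicate 1 and 0.0533 without mock replicate 3). EIN3 itself rose by 0.22 (adjusted p = 0.0215), a call that ended without 10 cGy replicate 2 (0.0752) or 3 (0.0537) and without mock replicate 2 (0.0868) or 3 (0.0601). The regulator gene SOG1 (-0.05) and the ACC synthase gene ACS6 (0.32) did not pass, and the sentinel genes SMR5 and ERF1 were below the filter. BGLU23, the only root marker that was measured, fell by 0.70 (adjusted p = 0.00966). In all, 4782 genes changed, 2560 up and 2222 down, and 285 rose and 54 fell by 2-fold or more. Without any 1 of the 6 libraries the number stayed between 3485 and 4185.

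**Figure D1:**
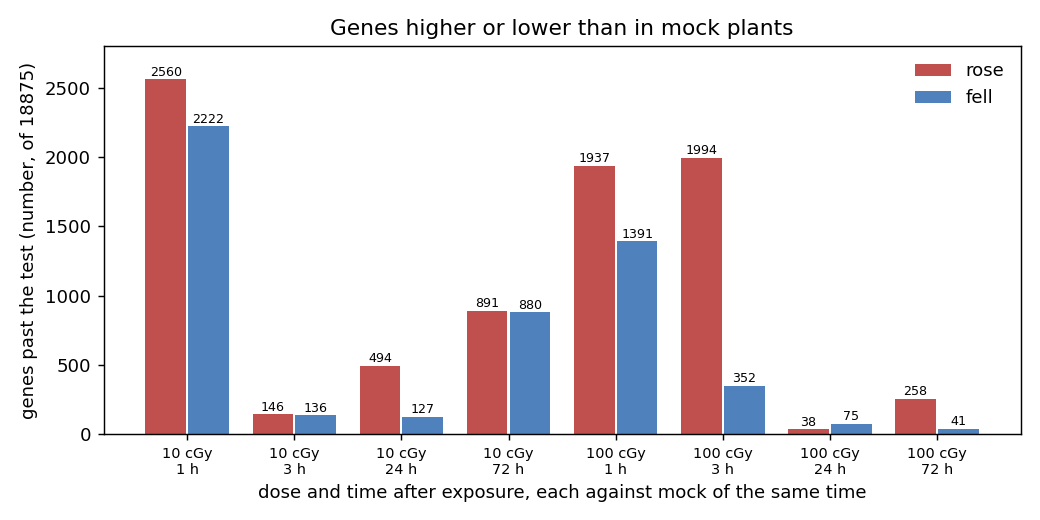
Number of genes that rose (red bars) or fell (blue bars) against mock plants of the same time, of 18875 tested with limma, for each dose and time on the horizontal axis. Most calls were made at 1 h, and after 100 cGy the bars for genes that rose exceed those for genes that fell at 3 h (1994 against 352), a difference that turned round when libraries were rescaled by median ratios (33.1% rose).

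At 1 h after 100 cGy, DNA damage response genes rose: 14 of 22 passed and 1 fell (14 and 2 adjusted over the list alone). XRI1 (AT5G48720) rose by 1.76 (SE 0.09, adjusted p = 1.4e-13), from 5.67 ± 0.354 CPM (SD, n = 3) in mock plants to 20.4 ± 1.57 CPM. PARP2 rose by 1.75 (SE 0.12, adjusted p = 1.45e-11), TSO2 by 0.85 (SE 0.09, adjusted p = 2.23e-08) and the thymidine kinase gene TK1A by 0.86. SMR7 rose by 1.37 (SE 0.18, adjusted p = 1.2e-06) at a level of 1.29 CPM against 0.194 CPM in mock plants, where the 0.5 added before the logarithm makes the log2 difference smaller than that of the means. BRCA1, of homologous recombination, rose by 0.60 (adjusted p = 0.000426), while GMI1 at 0.34 (adjusted p = 0.175), CYCB1;1 at 0.11 and SOG1 at 0.01 did not pass. The list had a camera adjusted p = 1.02e-09, and adjusted p = 0.111 with an estimated correlation. Of the 24 genes of DNA repair and damage signalling none rose and 5 fell, by both counts, among them ATRIP (-0.45, adjusted p = 4.86e-05), the end-joining gene KU80 (-0.27) and the UV damage-binding gene DDB2 (-0.31). That list's adjusted p = 0.0199 became adjusted p = 0.542 with an estimated correlation.

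The ethylene genes at 1 h after 100 cGy gave 8 rises of 21 in synthesis and signalling, by both counts (adjusted p = 0.00338; adjusted p = 0.202 with an estimated correlation). They again included EBF2 (0.51, SE 0.07, adjusted p = 7.84e-06), CTR1 (0.48, adjusted p = 3.96e-05), ERS1 (0.43) and ACS4 (1.02). EIN3 at 0.12 (adjusted p = 0.287) and ACS6 at -0.05 did not pass. Of 21 response factors and defence genes 6 rose and 1 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0106, and adjusted p = 0.542 with an estimated correlation). HRE1 rose by 1.59 (SE 0.13, adjusted p = 7.7e-10), ORA59 by 1.60, ERF2 by 2.04 and ERF5 by 0.85 (adjusted p = 0.00445), and ERF8, a repressor, stood at -0.54. Of 20 touch, wound and early stress genes 8 rose (9 adjusted over the list alone; adjusted p = 0.00178, and adjusted p = 0.657 with an estimated correlation), led by WRKY18 at 2.92 (SE 0.33, adjusted p = 1.56e-07). Of 23 jasmonate genes 8 rose (13 adjusted over the list alone; adjusted p = 0.000615, and adjusted p = 0.705 with an estimated correlation), with CYP94C1 at 2.33 and the repressor gene JAZ6 at 1.44. Heat shock genes fell, 4 of 10 (5 adjusted over the list alone). The coactivator gene MBF1C stood at -1.20 (SE 0.17, adjusted p = 7.67e-06) and the chaperone gene HSP101 at -0.75 (adjusted p = 0.000187). That list's adjusted p = 0.0204 became adjusted p = 0.542 with an estimated correlation and 0.0773 without mock replicate 1. The largest falls included the expansin gene EXPA8 at -1.91 (SE 0.28, adjusted p = 8.88e-06) and EXPB1 at -1.65. The largest rises again included AT1G72416 at 4.20 (SE 0.18, adjusted p = 7.92e-16), AT4G21870 at 4.00, AT5G61590 at 3.79 and PYL6 at 3.43. S-phase genes fell in 3 of 13 cases (4 adjusted over the list alone; adjusted p = 0.00182, and adjusted p = 0.542 with an estimated correlation). In all, 3328 genes changed, 1937 up and 1391 down, 198 and 40 of them by 2-fold or more, and 2402 to 2770 without any 1 library.

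The direct test between the doses at 1 h asked which genes follow the dose. It found 137 genes, 60 higher and 77 lower at 100 cGy, and DNA damage response genes stood out with 13 of 22 higher and none lower (camera adjusted p = 2.32e-35, and adjusted p = 0.000122 with an estimated correlation). XRI1 was higher by 1.41 (SE 0.09, adjusted p = 8.12e-11), PARP2 by 1.58 (SE 0.12, adjusted p = 1.74e-09), SMR7 by 1.45, TSO2 by 1.00, GMI1 by 0.92 and BRCA1 by 0.85. Each of these calls held without any 1 of the 6 libraries. In all, 23 genes were above both mock and 10 cGy plants at 100 cGy, 12 of them in the fixed lists. The other genes, chosen after their values were seen, include the telomere-repeat-binding family gene TRFL10 (1.38, SE 0.12, adjusted p = 2.45e-08) and AT2G45460 (1.28, SE 0.10, adjusted p = 4.85e-09). Others are AT5G60250 (1.48) and AT1G51130, which encodes an Nse4 subunit of the SMC5/6 repair complex (0.73, adjusted p = 0.00151). Heat shock genes were lower at 100 cGy in 4 of 10 cases (adjusted p = 1.53e-06, and adjusted p = 0.146 with an estimated correlation), as MBF1C by -1.23 (adjusted p = 8.66e-05). The zinc transporter genes IRT3 (-1.60, SE 0.17, adjusted p = 1.19e-06) and ZIP5 (-1.37, SE 0.16, adjusted p = 2.36e-06) were lower as well. Both, chosen after their values were seen, rose at 10 cGy alone: IRT3 by 1.67 (SE 0.17, adjusted p = 2.51e-08) to 66.64 CPM against 20.78 CPM in mock and 21.64 CPM at 100 cGy, and ZIP5 (adjusted p = 2.86e-07) to 8.452 CPM against 3.115 and 2.931 CPM. Against mock at 100 cGy IRT3 (0.07, adjusted p = 0.861) and ZIP5 (-0.08, adjusted p = 0.812) did not pass, and the calls at 10 cGy held without any 1 library. Without 10 cGy replicate 2 the test found 75 genes and without 100 cGy replicate 2 it found 70, and rescaled by median ratios 34.3% of 134 genes were higher, against 43.8% here.

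**Figure D2:**
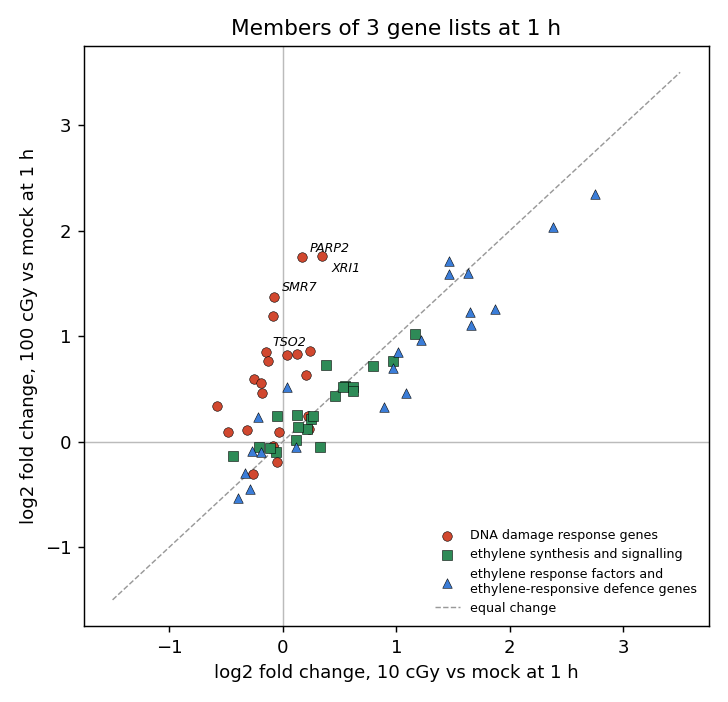
Log2 fold change against mock at 1 h after 10 cGy (horizontal axis) and after 100 cGy (vertical axis) for every measured gene of 3 lists, with the dashed line at equal change and 1 point per gene. Most DNA damage response genes (circles) lie above the line, as XRI1 with 0.35 and 1.76, and ethylene genes (squares and triangles) lie near it, as EBF2 with 0.53 and 0.51.

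Both doses called 2754 genes in the same direction at 1 h (1633 up and 1121 down) and 10 in opposite directions. Independent lists of these sizes would share 262.7 up and 163.8 down. Unchanged groups were simulated 100 times, with simulated mock libraries that both doses shared. They gave 0 calls at every time, so they set no level for the number of shared calls and serve for the fold changes only. EBF2, CTR1, ERS1, ACS4, HRE1, ORA59, ERF2, WRKY18 and CDF1 were among the genes that passed at both doses. The fold changes of the doses had a covariance across genes of 0.0971 against 0.0177 simulated, a difference of 0.0794, and a correlation of 0.838 against 0.506 (highest 0.766). Of all genes 81.63% had the same sign, against 66.67% simulated. Genes are not independent replicates, and part of the excess can come from the shared controls, since 3 mock libraries are too few to be divided.

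At 3 h after 10 cGy, the zinc transporter genes ZIP5 and ZIP4 rose and 6 genes of the iron-status list fell. ZIP5 (AT1G05300) rose by 1.83 (SE 0.16, adjusted p = 3.74e-08), from 10.3 ± 0.917 to 38.6 ± 8.16 CPM (SD, n = 3), and ZIP4 (AT1G10970) by 1.59 (SE 0.18, adjusted p = 7.89e-06). Of 9 iron-status genes 6 fell by both counts, among them IMA2 (AT1G47395), which encodes a peptide signal of iron shortage (-1.24, SE 0.17, adjusted p = 0.00022), and the iron-shortage transcription factor gene BHLH38 (-1.81, adjusted p = 0.0207). The list's adjusted p = 1.28e-06 was an adjusted p = 0.0493 with an estimated correlation, and its median was -1.16. BHLH38's call ended without 10 cGy replicate 1 (0.0968) or 2 (0.21) or mock replicate 1 (0.125), and that of IMA1 (-1.16, adjusted p = 0.0119) ended without 10 cGy replicate 2 (0.117) or mock replicate 1 (0.134). The chloroplast superoxide dismutase gene CSD2 fell by 0.57 (SE 0.10, adjusted p = 0.0033), and the lipase family gene AT1G54010 rose by 1.58 (SE 0.24, adjusted p = 0.000824). S-phase genes fell, 7 of 13 (1 up and 11 down adjusted over the list alone; 5 after rescaling by median ratios; adjusted p = 1.19e-08, and adjusted p = 0.295 with an estimated correlation). MCM2 (-0.40, adjusted p = 0.011) lost its call without 10 cGy replicate 2 (0.16) or mock replicate 1 (0.0913). Of 12 flavonoid genes 2 rose (7 adjusted over the list alone; adjusted p = 2.6e-07, and adjusted p = 0.295 with an estimated correlation), as the chalcone isomerase gene CHI (0.52, adjusted p = 0.0103, but 0.0545 without 10 cGy replicate 2). No jasmonate gene passed singly, with a list median of 1.0980 and adjusted p = 3.83e-11 (adjusted p = 0.455 with an estimated correlation). Of the DNA damage sentinels PARP2 (0.02), XRI1 (-0.16), BRCA1 (-0.17), GMI1 (0.23), TSO2 (-0.30), SMR7 (-0.13) and CYCB1;1 (0.19) did not pass. SOG1 fell by 0.42 (adjusted p = 0.0395), a call that ended without 10 cGy replicate 1 (0.0788) or 2 (0.345) or mock replicate 1 (0.16), 2 (0.06) or 3 (0.094). EBF2 (0.12), EIN3 (0.09), ACS6 (0.11) and ERF5 (-0.10) did not pass. In all, 282 genes changed, 146 up and 136 down, 51.8% up against 62.3% of 300 after rescaling by median ratios. The count was 19, 137 or 470 without mock replicate 1, 2 or 3, and 73, 19 or 664 without 10 cGy replicate 1, 2 or 3. Replicate 1 of 10 cGy stood apart in its RNA, with the highest shares of all 36 libraries from chloroplast genes (0.608%, next 0.331%), mitochondrial genes (0.0131%, next 0.0085%) and genes with ENSRNA identifiers (0.435%, next 0.335%). Without it the iron-status and S-phase lists kept their calls, as did ZIP4 and ZIP5.

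At 3 h after 100 cGy, DNA damage response genes were still up, 7 of 22 (12 adjusted over the list alone). PARP2 rose by 1.32 (SE 0.12, adjusted p = 1.26e-07), from 7.68 to 19.9 CPM, and XRI1 by 0.77 (SE 0.09, adjusted p = 2.33e-05). GMI1 rose by 0.83 (SE 0.17, adjusted p = 0.00295), TK1A by 0.44 and the cell cycle inhibitor gene KRP6 by 0.64 (adjusted p = 0.00144). TSO2 (0.13), BRCA1 (0.17), SMR7 (0.50, adjusted p = 0.0589), CYCB1;1 (0.28) and SOG1 (0.01) did not pass. The list had a camera adjusted p = 0.000103, and adjusted p = 0.455 with an estimated correlation. Of the repair genes 5 of 24 rose by both counts, ATRIP by 0.41 (adjusted p = 0.00145), against 1 after rescaling (list adjusted p = 0.178). Iron-status genes fell, 6 of 9 by both counts, with BHLH38 at -1.92 (SE 0.40, adjusted p = 0.00389), BHLH39 at -1.73, BHLH100 at -1.68, IMA1 at -1.15 (adjusted p = 0.00327) and IMA2 at -1.21 (SE 0.17, adjusted p = 0.00018). Their list median was -1.15, with an adjusted p = 1.42e-08, and adjusted p = 0.0225 with an estimated correlation. ZIP5 stood at 36.2 ± 6.7 CPM and ZIP4 at 25.1 ± 5.72 CPM, against 10.3 ± 0.917 and 9.6 ± 0.182 CPM (SD, n = 3) in mock plants.

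**Figure D3:**
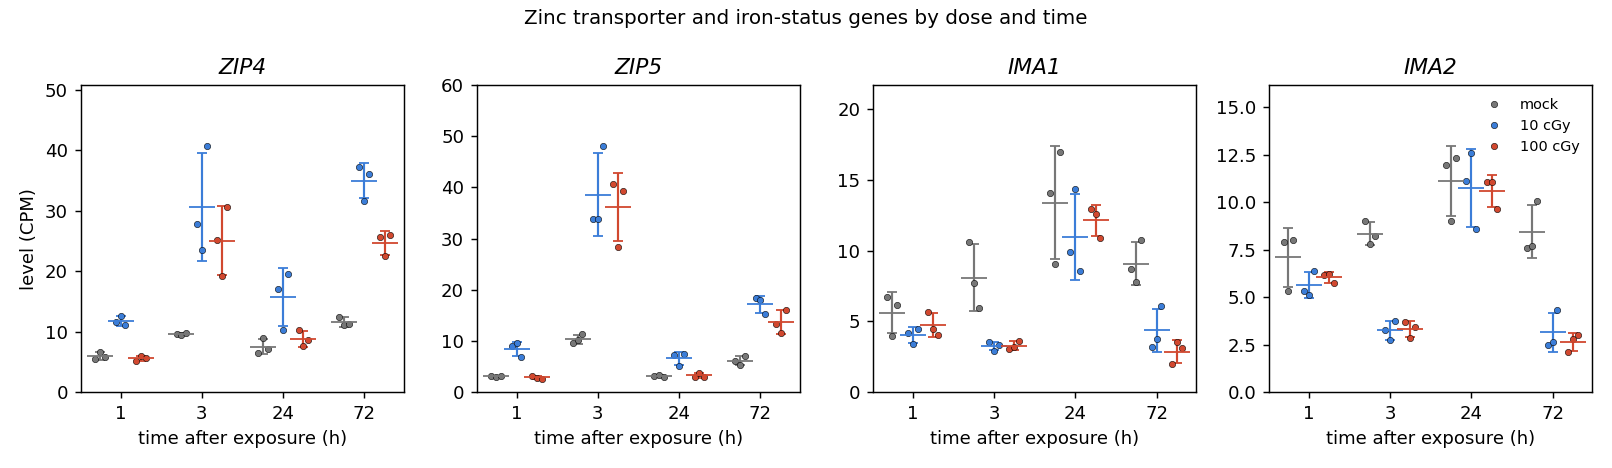
Levels (CPM) of the zinc transporter genes ZIP4 and ZIP5 and the iron-shortage peptide genes IMA1 and IMA2 against hours after exposure, with 1 point per library, a dash at the mean of 3 libraries and bars of 1 SD, for mock (grey), 10 cGy (blue) and 100 cGy (red). At 3 h ZIP5 lies at 38.6 and 36.2 CPM after the 2 doses against 10.3 CPM in mock plants, and IMA2 at 3.26 and 3.33 CPM against 8.36 CPM.

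Cold-responsive genes rose at 3 h after 100 cGy, 4 of 9 (6 adjusted over the list alone; adjusted p = 0.000812, and adjusted p = 0.455 with an estimated correlation). Examples are COR15B, which protects membranes from freezing (0.71, SE 0.14, adjusted p = 0.0021), and GOLS3, a galactinol synthase gene (0.77). Photosynthesis genes fell, 11 of 22 (13 adjusted over the list alone, 13 after rescaling; adjusted p = 5.36e-14, and adjusted p = 0.295 with an estimated correlation). They include the Rubisco small subunit genes RBCS3B (-0.34, SE 0.06, adjusted p = 0.00138) and RBCS1B (-0.42), near-identical copies whose shared reads leave the split between them uncertain. Of 12 flavonoid genes 2 rose (4 adjusted over the list alone), FLS1 for flavonol synthase by 0.63 (SE 0.09, adjusted p = 0.00018) and CHI by 0.57 (adjusted p = 0.00132). The list's adjusted p = 0.0456 became 0.091 or 0.0893 without mock replicate 1 or 2, 0.228 without 100 cGy replicate 1 and adjusted p = 0.705 with an estimated correlation. Clock genes gave 6 rises of 22 (9 up and 1 down adjusted over the list alone), 1 up and 1 down after rescaling. Their adjusted p = 0.0374 became 0.0806 on rescaling, 0.191 without mock replicate 1, 0.152 without 100 cGy replicate 2 and adjusted p = 0.542 with an estimated correlation. RVE1 rose by 0.59 (adjusted p = 0.00312). Of 13 S-phase genes 1 rose and 3 fell (1 and 4 adjusted over the list alone, 0 and 6 after rescaling; adjusted p = 6.54e-06, and adjusted p = 0.455 with an estimated correlation). In ethylene signalling EBF2 rose by 0.30 (adjusted p = 0.0111) and ERS1 by 0.31 (adjusted p = 0.0145), and on rescaling neither passed (0.0749 and 0.111). EBF2's call also ended without 100 cGy replicate 2 (0.074) or mock replicate 1 (0.099) and that of ERS1 without mock replicate 1 (0.0768). EIN3 (0.17) and ACS6 (0.33) did not pass, and ERF5 rose by 0.73 (adjusted p = 0.0251), but not on rescaling (0.0629) or without 100 cGy replicate 1 (0.0604) or 2 (0.0858) or mock replicate 2 (0.146). SOC1, the only measured flowering marker, rose by 0.73 (adjusted p = 0.0108, but 0.0654 without 100 cGy replicate 2 and 0.0564 without mock replicate 2). In all, 2346 genes changed, 1994 up (85%) and 352 down, and 93 and 13 by 2-fold or more. After rescaling by median ratios 33.1% of 1434 genes were up, and without 100 cGy replicates 2 and 3 together, which stood apart on principal component 5 (-23.5 and -22.2 against 5.08 for replicate 1), 47.9% of 117. Singly, the count was 3544, 529 or 1360 without 100 cGy replicate 1, 2 or 3 and 823 or 1253 without mock replicate 1 or 2.

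Between the doses at 3 h, several lists differed, and none held with an estimated correlation. Of 22 DNA damage response genes 11 were higher at 100 cGy (5 after rescaling; adjusted p = 1.2e-07, and adjusted p = 0.146 with an estimated correlation). PARP2 was higher by 1.30 (adjusted p = 3.59e-07) and XRI1 by 0.93 (adjusted p = 7.97e-07), and both calls held on rescaling and without any 1 library. Heat shock genes were lower in 3 of 10 cases (adjusted p = 1.14e-06, and adjusted p = 0.146 with an estimated correlation), and IGMT2, for a methyltransferase of indole glucosinolates, was higher by 1.83 (SE 0.36, adjusted p = 0.00237). Clock genes gave 12 of 22 higher but 3 after rescaling (adjusted p = 7.11e-06, and adjusted p = 0.146 with an estimated correlation). Photosynthesis genes had the lowest p, with 4 of 22 lower and 9 after rescaling (adjusted p = 2.69e-12, and adjusted p = 0.304 with an estimated correlation). DNA repair and damage-signalling genes gave 8 of 24 higher and 2 after rescaling (adjusted p = 0.000604, and adjusted p = 0.422 with an estimated correlation). In all, 2372 genes differed, 93.5% of them higher at 100 cGy, where the median of all genes lay 0.11 above that at 10 cGy, and after rescaling 33.7% of 921 genes were higher. The count was 1346 or 822 without 10 cGy replicate 1 or 2, and 4342, 427 or 1158 without 100 cGy replicate 1, 2 or 3. Both doses called 140 genes in the same direction at 3 h (107 up and 33 down), against 15.42 and 2.536 for independent lists. Their fold changes had a covariance of 0.0498 against 0.0162 (difference 0.0336) and a correlation of 0.684 against 0.478 (highest 0.823). Of all genes 60.25% had the same sign, fewer than the 66.58% simulated. That overlap was 13, 47 or 271 without mock replicate 1, 2 or 3, 37, 19 or 288 without 10 cGy replicate 1, 2 or 3 and 73 without 100 cGy replicate 2. After rescaling it was 107 genes, 85 of them among the 140.

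**Figure D4:**
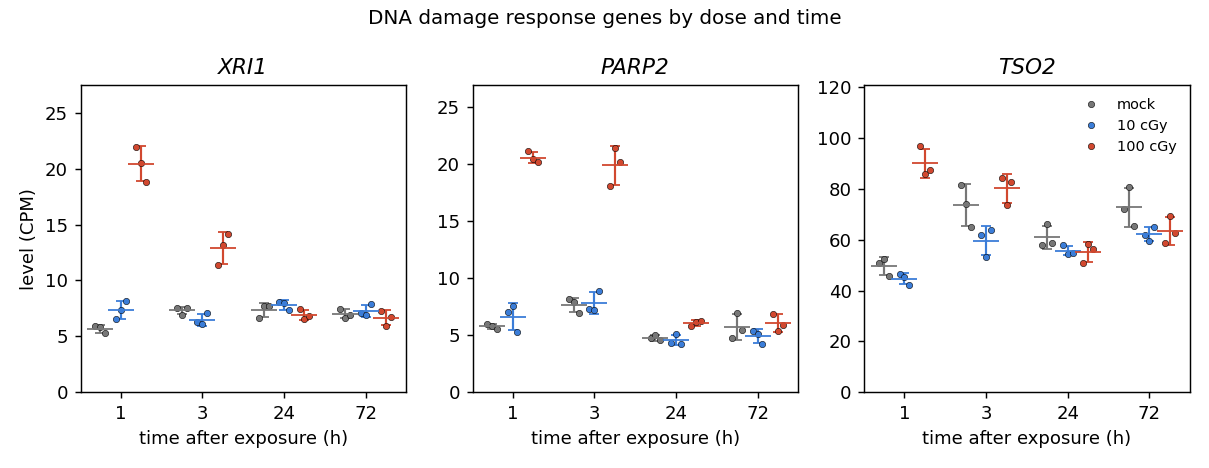
Levels (CPM) of the DNA damage response genes XRI1, PARP2 and TSO2 against hours after exposure, with 1 point per library, a dash at the mean of 3 libraries and bars of 1 SD, for mock (grey), 10 cGy (blue) and 100 cGy (red). At 1 h the 100 cGy means are 20.4, 20.6 and 90 CPM against 5.67, 5.77 and 49.7 CPM in mock plants.

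A day after exposure few genes stood apart by 2-fold. After 10 cGy the early light-induced gene ELIP1 fell by 0.83 (SE 0.15, adjusted p = 0.00282), the clock gene GI by 0.50 (SE 0.09, adjusted p = 0.00176) and FLS1 by 0.54 (SE 0.09, adjusted p = 0.00133). AT1G10150 rose by 1.24 (SE 0.19, adjusted p = 0.000579) and TPS8, of the trehalose phosphate synthase family, by 1.21 (SE 0.19, adjusted p = 0.000836). ZIP4 (0.98, adjusted p = 0.0025) and ZIP5 (0.94, adjusted p = 0.00119), chosen after their values were seen, rose too, as they did after 10 cGy at the other times, and both calls held without any 1 library. At 100 cGy they did not pass at 24 h (0.22 and 0.03). Of 12 flavonoid genes 3 fell by both counts, and the list test pointed down (adjusted p = 0.046) although its median was 0.33. That call ended on rescaling (0.282), without 10 cGy replicate 1 (0.569) or mock replicate 2 (0.179) or 3 (0.0599), and gave adjusted p = 0.705 with an estimated correlation. EBF2 rose by 0.29 (adjusted p = 0.0309), which ended on rescaling (0.09) and without 10 cGy replicate 2 (0.0606) or 3 (0.292) or mock replicate 1 (0.196) or 3 (0.0564). The 2 rises among ethylene signalling genes became 0 on rescaling (list adjusted p = 0.178). EIN3 (0.19), ACS6 (-0.00), ERF5 (0.39) and the damage sentinels PARP2 (-0.06), XRI1 (0.08), BRCA1 (-0.06), GMI1 (0.13), TSO2 (-0.13), SMR7 (0.01), CYCB1;1 (-0.28) and SOG1 (0.14) did not pass. The 22 DNA damage response genes lay lower as a list with 0 past the test singly (adjusted p = 0.0183, 0.0734 without mock replicate 2, 0.133 without 10 cGy replicate 2, and adjusted p = 0.542 with an estimated correlation). In all, 621 genes changed, 494 up and 127 down (79.6% up, against 34.0% of 509 after rescaling), and 177 or 404 without mock replicate 1 or 3 and 110 without 10 cGy replicate 3. These calls were not kept with only the libraries of 24 h in the fit.

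After 100 cGy at 24 h the phospholipase gene PLC1 rose by 0.65 (SE 0.10, adjusted p = 0.00419), the only call taken by the naming rule that held without any 1 library. ELIP1 fell by 1.00 (SE 0.15, adjusted p = 0.00419, but 0.0748 without 100 cGy replicate 3). Genes of G2 and mitosis lay lower as a list, with 0 of 20 passing singly and 11 falling when adjusted over the list alone (median -0.37, adjusted p = 1.81e-09, and adjusted p = 0.295 with an estimated correlation). Of the 19 DNA methylation and silencing genes 0 passed, and the list lay lower (adjusted p = 0.0106, 0.0734 without mock replicate 2, 0.0583 without 100 cGy replicate 2, and adjusted p = 0.542 with an estimated correlation). Of the sentinels printed here none passed, with PARP2 at 0.32 (adjusted p = 0.202), XRI1 at -0.08, BRCA1 at -0.10 and GMI1 at 0.27. TSO2 stood at -0.14, SMR7 at 0.27, CYCB1;1 at -0.56 (adjusted p = 0.0952), SOG1 at -0.13, EBF2 at -0.08, EIN3 at 0.07, ACS6 at 0.05 and ERF5 at 0.11. In all, 113 genes changed, 38 up and 75 down (33.6% up, against 49.5% of 91 after rescaling), and 51 with the replicate number as a block, the comparison in which same-numbered libraries deviated together. The count was 6, 17 or 34 without mock replicate 1, 2 or 3 and 38 or 1 without 100 cGy replicate 1 or 3. Between the doses 213 genes differed (12.7% higher at 100 cGy, against 80.4% of 153 after rescaling), among them ZIP5, lower by -0.91 (SE 0.16, adjusted p = 0.00747, but 0.0891 without 10 cGy replicate 3). That count was 6 without 10 cGy replicate 3 and 31, 54 or 138 without 100 cGy replicate 1, 2 or 3. With only the libraries of 24 h in the fit, nearly all of the 113 and of the 213 calls ended. Both doses called 32 genes in the same direction (18 up and 14 down), against 0.9945 and 0.5046 for independent lists. Their fold changes had a covariance of 0.0172 against 0.0150 (difference 0.0022) and a correlation of 0.452 against 0.498 (highest 0.770), and 64.24% had the same sign against 66.67%, neither above the simulated mean. The overlap was 3, 12 or 17 without mock replicate 1, 2 or 3, 21 or 12 without 10 cGy replicate 1 or 3, and 20 or 1 without 100 cGy replicate 1 or 3. After rescaling it was 29 genes, 20 of them among the 32.

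After 72 h ZIP4, ZIP5 and IMA2 differed from mock. At 10 cGy ZIP4 rose by 1.55 (SE 0.18, adjusted p = 2.03e-05), ZIP5 by 1.41 (SE 0.16, adjusted p = 1.36e-05), and IMA2 fell by 1.32 (SE 0.17, adjusted p = 0.000174). Of the iron-status list 2 of 9 fell by both counts (adjusted p = 0.0456). That call ended on rescaling (0.0768), without mock replicate 1 (0.155) or 3 (0.0579) or 10 cGy replicate 1 (0.0577) or 2 (0.0508), and at adjusted p = 0.489 with an estimated correlation. The catalase gene CAT3 rose by 0.63 (SE 0.12, adjusted p = 0.00271), the DNA demethylase gene DML2 by 0.37 (SE 0.07, adjusted p = 0.00171) and the salicylate receptor gene NPR1 by 0.35. ELIP2 fell by 1.68 (SE 0.25, adjusted p = 0.000534). Of 19 salicylate and immune genes 5 rose (8 adjusted over the list alone, 3 after rescaling; adjusted p = 0.000146, and adjusted p = 0.455 with an estimated correlation). S-phase genes fell in 3 of 13 cases (9 adjusted over the list alone; adjusted p = 6.3e-06, and adjusted p = 0.455 with an estimated correlation). Genes of G2 and mitosis fell in 2 of 20 (5 adjusted over the list alone; adjusted p = 1.65e-06, and adjusted p = 0.455 with an estimated correlation). In ethylene signalling 3 of 21 rose by both counts (adjusted p = 0.0317, 0.0593 without mock replicate 3, 0.0698 without 10 cGy replicate 3, and adjusted p = 0.455 with an estimated correlation). EIN3 rose by 0.26 (adjusted p = 0.0164, but 0.0636 or 0.0797 without 10 cGy replicate 1 or 2 and 0.145 without mock replicate 2). EBF2 rose by 0.23 (adjusted p = 0.048, lost without any 1 of the 6 libraries: 0.168, 0.115 or 0.0671 without 10 cGy replicate 1, 2 or 3 and 0.151, 0.0955 or 0.0828 without mock replicate 1, 2 or 3). ACS6 (-0.01), ERF5 (0.12), PARP2 (-0.19), XRI1 (0.05), BRCA1 (-0.17), GMI1 (0.23), TSO2 (-0.22), SMR7 (-0.06), CYCB1;1 (-0.46, adjusted p = 0.0682) and SOG1 (0.21) did not pass. The DNA damage response list lay lower, with 1 of 22 called down and 0 when adjusted over the list alone (adjusted p = 0.0106, and adjusted p = 0.542 with an estimated correlation). In all, 1771 genes changed, 891 up and 880 down (50.3% up, against 41% of 1843 after rescaling), and 500 without mock replicate 2 and 822, 982 or 1138 without 10 cGy replicate 1, 2 or 3.

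At 72 h after 100 cGy, IMA2 fell by 1.51 (SE 0.17, adjusted p = 3.52e-05), from 8.45 to 2.65 CPM, the only call taken by the naming rule that held without any 1 library. IMA1 fell by 1.52 (adjusted p = 0.00312, but 0.0578 without 100 cGy replicate 1). ZIP5, chosen after its values were seen, rose by 1.09 (adjusted p = 0.00119), which held without any 1 library, and ZIP4 by 1.05 (adjusted p = 0.00774), which held without 4 of 6. On principal component 3 replicates 1 and 2 of this group lay at -16.07 and -7.45, and replicate 3 at 25.28, among the mock and 10 cGy libraries of 72 h (19.95 to 39.87). Of 9 iron-status genes 4 fell (1 up and 5 down adjusted over the list alone; median -1.38, adjusted p = 1.8e-05, and adjusted p = 0.0989 with an estimated correlation). Senescence and sugar-starvation genes lay higher as a list, with 0 of 12 passing singly and 9 rising when adjusted over the list alone (median 1.08, adjusted p = 1.78e-05, and adjusted p = 0.455 with an estimated correlation). Replicates 1 and 2 carried this: their list medians lay 1.86 and 1.58 above the mean of mock, replicate 3 at 0.31, and mock libraries from -0.61 to 0.84. The 13 abscisate and dehydration genes had a median of 0.87 with 0 passing by either count (adjusted p = 0.000137, and adjusted p = 0.542 with an estimated correlation), and the replicates lay at 1.45, 0.72 and 0.23. Of 19 antioxidant genes 4 rose (7 up and 1 down adjusted over the list alone; adjusted p = 0.00817, 0.155 without 100 cGy replicate 1, and adjusted p = 0.542 with an estimated correlation), with replicates at 0.43, 0.30 and 0.03. In the iron-status list all 3 replicates lay low (-1.76, -1.24 and -0.85). The salicylate and immune, S-phase, and G2 and mitosis lists were called as after 10 cGy (camera adjusted p = 0.00174, 7.14e-05 and 3.17e-05). With an estimated correlation these were adjusted p = 0.542, 0.455 and 0.455. Their replicates lay at 0.25, 0.27 and 0.45, at -0.31, -0.04 and -0.13, and at -0.29, -0.10 and -0.24. In the last 2 of these lists replicate 2 lay within the range of the mock libraries. CAT3 rose by 0.64 (adjusted p = 0.0123, but 0.131 without 100 cGy replicate 1 and 0.0527 or 0.0988 without mock replicate 1 or 2). EIN3 rose by 0.28 (adjusted p = 0.0439), which ended on rescaling (0.114), without 100 cGy replicate 1 (0.231) or 3 (0.0529) and without mock replicate 1 (0.152) or 2 (0.223). Of 21 genes for ethylene synthesis and signalling 1 rose (2 adjusted over the list alone; adjusted p = 0.0485, and adjusted p = 0.455 with an estimated correlation). That list call ended on rescaling (0.0502), without mock replicate 2 (0.0681) or 3 (0.099) and without 100 cGy replicate 2 (0.0789) or 3 (0.0677). The ethylene response factor and defence list lay higher with 0 of 21 passing singly and 4 rising when adjusted over the list alone (adjusted p = 0.00186, and adjusted p = 0.455 with an estimated correlation). EBF2 (0.27, adjusted p = 0.0549), ACS6 (0.21), ERF5 (0.31), PARP2 (0.09), XRI1 (-0.07), BRCA1 (-0.08), GMI1 (0.34), TSO2 (-0.19), SMR7 (0.03), CYCB1;1 (-0.16) and SOG1 (0.08) did not pass. In all, 299 genes changed, 258 up and 41 down (86.3% up, against 61.5% of 221 after rescaling), and 15, 5 or 751 without mock replicate 1, 2 or 3 and 2 or 740 without 100 cGy replicate 1 or 3. Between the doses limma found 0 genes at 72 h, with 1869 at an unadjusted p under 0.05, and 27 or 399 without 100 cGy replicate 1 or 3. Both doses called 133 genes in the same direction (100 up and 33 down), against 12.18 and 1.912 for independent lists. Their fold changes had a covariance of 0.0465 against 0.0175 (difference 0.0291) and a correlation of 0.620 against 0.499 (highest 0.799), and 79.54% had the same sign against 66.79%. The overlap was 15, 4 or 351 without mock replicate 1, 2 or 3, 62, 70 or 81 without 10 cGy replicate 1, 2 or 3, and 2 without 100 cGy replicate 1. After rescaling it was 110 genes, 78 of them among the 133.

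Tests of the difference between times asked whether the response to a dose changed with time, and the genes named here were chosen after their values were seen. From 1 to 3 h the 10 cGy response of AT1G72416 fell by 5.25 (SE 0.25, adjusted p = 2.11e-14), of AT4G21870 by 4.81 (SE 0.34, adjusted p = 1.65e-10) and of the abscisate receptor gene PYL5 by 2.77 (SE 0.30, adjusted p = 1.15e-07). The 100 cGy response of the same genes fell by 4.65, 4.27 and 2.95. ZIP5 moved the other way at 100 cGy, by 1.82 (SE 0.22, adjusted p = 1.27e-06). Its response fell by 1.71 from 3 to 24 h (SE 0.22, adjusted p = 0.000104), as did that of ELIP1 by 1.57 (SE 0.22, adjusted p = 0.000223). From 3 to 24 h the 10 cGy response of SIB1, for a sigma factor binding protein, rose by 1.67 (SE 0.32, adjusted p = 0.00651). The 10 cGy response differed between 1 and 3 h for 2759 genes, between 3 and 24 h for 510 (81.6% higher at 24 h, against 37.1% of 267 after rescaling). Between 24 and 72 h it differed for 0 by limma, with 1932 at an unadjusted p under 0.05. The 100 cGy response differed for 2157 (68.5% higher at 3 h, against 40.1% of 2030 after rescaling), 545 (23.5% higher at 24 h, against 76.3% of 354, with a median of all genes of -0.11) and 1, IMA2 (-1.45, adjusted p = 0.0419). For 10 cGy from 3 to 24 h the count was 124 or 334 without mock 3 h replicate 1 or 2 and 263 or 132 without 10 cGy 3 h replicate 1 or 2. It was 247 or 305 without mock 24 h replicate 1 or 2, and 252 or 163 without 10 cGy 24 h replicate 1 or 3. For 100 cGy from 3 to 24 h it was 186 or 348 without mock 3 h replicate 1 or 2 and 1447, 143 or 333 without 100 cGy 3 h replicate 1, 2 or 3. It was 354 or 195 without mock 24 h replicate 1 or 2, and 178 without 100 cGy 24 h replicate 3.

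Mock plants served as the background of time and of the hour of harvest. From 1 to 3 h the morning clock gene LHY fell by 3.66 (SE 0.11, adjusted p = 3.63e-20) and the B-box gene BBX32 fell by 3.66 (SE 0.15, adjusted p = 1.25e-17). VSP1, a vegetative storage protein gene, rose by 3.71 (SE 0.77, adjusted p = 0.000233). The heat shock factor gene HSFA2 was higher at 24 h than at 1 h by 3.27 (SE 0.32, adjusted p = 3.06e-09), and TPS8 higher at 72 h by 2.75 (SE 0.19, adjusted p = 5.65e-12). These genes were chosen after their values were seen. In all, 8320 genes differed at 3 h (4534 higher and 3786 lower), 7249 at 24 h (3828 and 3421) and 6298 at 72 h (3482 and 2816). Of the damage sentinels printed here TSO2 (0.56, adjusted p = 5.98e-06), BRCA1 (0.60, adjusted p = 0.000117), XRI1 (0.34, adjusted p = 0.00342) and PARP2 (0.38, adjusted p = 0.0114, but 0.0509 without mock 3 h replicate 1) were higher in mock plants at 3 h than at 1 h. Of the ethylene sentinels EBF2 was lower (-0.32, adjusted p = 0.000756) and ERF5 higher (0.53, adjusted p = 0.043), the latter lost without 4 of 6 single libraries.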

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

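Of the tests in this part, only the one on a few abundant genes was written before its result was seen, and the others were chosen afterwards. The results listed first were singled out because a dose's effect differed between 2 successive times by limma's test of the difference itself, and the rule for a library far from the others is not applied to groups of 3 libraries.

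The 10 cGy effect differed between 1 and 3 h for 2759 genes and between 3 and 24 h for 510. The 100 cGy effect differed for 2157 genes, 545 genes and, from 24 to 72 h, 1 gene. From 1 to 3 h after 10 cGy the effect on XRI1 changed by -0.51 (adjusted p = 0.00784 by limma), on EBF2 by -0.41 (0.00727), on ERF5 by -1.12 (0.0106) and on GMI1 by 0.81 (0.0174). GMI1's call ended without mock 1 h replicate 3 (0.0519), 10 cGy 1 h replicate 1 (0.0629) or mock 3 h replicate 3 (0.0694). From 3 to 24 h after 10 cGy SOG1 changed by 0.56 (0.0422 by limma), a call that 9 of 12 single libraries and rescaling (0.111) ended. From 1 to 3 h after 100 cGy TSO2 changed by -0.72 (0.000164 by limma), XRI1 by -0.99 (5.98e-06) and SMR7 by -0.87 (0.0212), the last ending without mock 1 h replicate 3 (0.0711) or 100 cGy 1 h replicate 2 (0.066). From 3 to 24 h after 100 cGy PARP2 changed by -0.9998 (0.00323 by limma), XRI1 by -0.85 (0.00116), CYCB1;1 by -0.84 (0.0423) and EBF2 by -0.38 (0.048). The call on CYCB1;1 ended without 10 of 12 single libraries and on rescaling (0.0704), and that on EBF2 without 9 of 12 and on rescaling (0.163). IMA2, the 1 gene from 24 to 72 h, lost its call without 8 of 12 single libraries.

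Pattern: 2754 genes were called in the same direction after both doses at 1 h, although the doses differ 10-fold. For the hour of harvest, 9.56% of the summed squared effect lay in the plane of the other mock groups, where the change of mock plants from 1 to 3 h had 59.5% over the same genes. That change shares the mock 3 h libraries with the plane, and the other mock groups sample few hours. The 9.56% shows only that the effect was unlike the differences among those mock groups, and the hour of harvest stays undecided. Against the scaling of libraries, 2807 genes were called so after rescaling, 2604 of them among the 2754. Darkness of the irradiated plants is undecided: dark-induced genes exceeded light-induced genes by 0.3454 after 10 cGy and 0.4817 after 100 cGy, with 5 of 17 dark-induced genes called up at each dose and 1 called down after 10 cGy. Of 11 light-induced genes, which darkness would lower, 3 rose and 2 fell after 10 cGy (median -0.03), and 1 rose and 3 fell after 100 cGy (-0.13). Against random lists of genes of like level, the dark-induced medians at 1 h lay at percentiles 99.99 and 100 after 10 and 100 cGy. The light-induced medians lay at 53.06 and 2.13. Genes of random lists need not vary together, so these percentiles do not decide. Shifts of dark-induced or light-induced genes were not confined to 1 h. At 24 h after 10 cGy 0 light-induced genes rose and 6 fell (median -0.42), and the dark-induced median was 0.22. At 24 h after 100 cGy the medians were -0.18 and 0.03, with 0 genes called. Dark-induced medians at 3 and 72 h were 0.13 and 0.20 after 10 cGy and 0.23 and 0.30 after 100 cGy. Light-induced medians at these times were -0.01 and -0.01 after 10 cGy and 0.14 and -0.04 after 100 cGy. Handling common to irradiated plants, such as transport to the source, could produce such a pattern, and no group in the labels separates it from radiation. Genes higher at 100 cGy than at 10 cGy, as XRI1 (1.41) and PARP2 (1.58), come from a test between the doses, which leaves out what both exposed groups share. Anything besides dose that differed between the 10 cGy and 100 cGy plants, such as handling or trays, stays in that test.

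Pattern: iron-status genes were lower and ZIP4 and ZIP5 higher at 3 h after both doses, and at 1 h ZIP4 (0.92) and ZIP5 rose after 10 cGy alone (ZIP4 -0.09 and ZIP5 -0.08 at 100 cGy), as at 24 h (0.98 and 0.94, against 0.22 and 0.03). The iron genes BHLH38 and BHLH39 had low means at 1 h already, 0.83 and 0.38 CPM after 10 cGy against 3.65 and 1.96 CPM in mock. After 100 cGy these means were 2.02 and 1.22 CPM, and 0 of 9 iron-status genes were called different between the doses at 1 h. For the hour of harvest, 88.9% of the 9 called iron and zinc genes lay outside the range of the 4 mock means at both doses, BHLH101 being the exception. These genes were taken because they were called against mock at 3 h, and the 4 mock times sample few hours. The share therefore does not decide on the hour of harvest. Trays or soil stay open: ZIP5 was called lower at 100 cGy than at 10 cGy at 2 times (-1.37 at 1 h and -0.91 at 24 h), and the labels name no trays. If trays differed in metal supply, these genes could differ without radiation, and no biological explanation was tested.

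Pattern: at 3 h after 100 cGy far more genes rose than fell (85% rose). This share was 33.1% after rescaling by median ratios and 47.9% without replicates 2 and 3. Rescaling centres the fold changes and so itself sets this share, and the other fit leaves 1 library, so neither tells the cause. Without the 100 most abundant genes, which hold 28.2% of reads, it was 67.6% of 1401 genes, which leaves their part undecided. Rises such as PARP2 (1.32) and falls such as IMA2 (-1.21) passed under either scaling, and no biological explanation of the excess was tested.

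Exchanged labels give 10 splits for 3 against 3 libraries, so a share never falls under 0.1. The real labels gave the most calls (1 split of 10 as high) in 13 comparisons. With the real count and the highest other, these were 4782 and 0, 282 and 20, 621 and 245, and 1771 and 0 for 10 cGy at 1, 3, 24 and 72 h. For 100 cGy they were 3328 and 0, 2346 and 162, 113 and 1, and 299 and 149. Between the doses they were 137 and 1 at 1 h and 2372 and 4 at 3 h, and in mock plants 8320 and 0, 7249 and 2, and 6298 and 0. Between the doses at 24 h 2 of 10 splits reached the real 213 (highest other 305), and at 72 h all 10 reached 0 (highest other 1). Of 100 drawn splits for differences between times, 1, 2 and 100 reached the real 2759, 510 and 0 for 10 cGy (highest others 2628, 1052 and 3039). For 100 cGy 3, 4 and 20 reached 2157, 545 and 1 (highest others 3977, 874 and 1035). Without draws that exchange 1 whole time and nothing else, the highest others were 2628, 1052 and 668 for 10 cGy and 2810, 874 and 1035 for 100 cGy. In each of these tests the draw with the highest count exchanged 2 or 3 of the 3 labels at 1 of the times. Such an exchange reverses the sign of the effect at that time, in full size with 3 labels and in smaller size with 2. The difference between times thus moves toward a sum. High counts can follow from this, which was not tested, so they do not by themselves show a structure of the samples.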

How the results depend on the processing

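All tests in this part that concern overlaps, differences between times, mock times and the fit without 2 libraries were chosen after the data were seen. No called direction of a named gene reversed under any setting, and pseudocounts of 0.1 and 1 and the authors' log table moved no count by over 1.5 times. Of 393 named results, not all of them called, 11 lost their call with a pseudocount of 0.1, 4 with 1, 54 without a filter, 36 on rescaling, 127 with the libraries of 1 time only, 37 with a block and 20 with array weights. Without 1 library 561 of 2358 did. Under a stricter filter all 289 results still tested stayed on the same side of the threshold. Planned count-based tests with edgeR and DESeq2 were not run, since whole reads were recovered for most values but not for all. Depth limits genes near the floor of 3 counts (0.0818 to 0.136 CPM).

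Without a filter more genes were tested, and the counts were 153 (10 cGy, 3 h), 54 (100 cGy, 24 h), 181 (100 cGy, 72 h), 2 (between doses, 72 h) and 299 (10 cGy, 24 h minus 3 h). Overlaps were 73, 17 and 78 at 3, 24 and 72 h. With the stricter filter 349 genes differed between doses at 24 h. Rescaling gave 1434 (100 cGy, 3 h), 921 (between doses, 3 h), 267 (10 cGy, 24 h minus 3 h), 1 (10 cGy, 72 h minus 24 h) and 354 (100 cGy, 24 h minus 3 h). The cause was not tested.

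With fewer libraries in the fit, those of the time alone, the counts were 80 (between doses, 1 h) and 24, 512 and 69 (10 cGy, 100 cGy and between doses, 3 h). They were 0, 1 and 1 (the same at 24 h, the 0 with 2688 genes at an unadjusted limma p under 0.05) and 693 and 41 (10 and 100 cGy, 72 h). Overlaps were 12, 0 and 33. With the libraries of the times compared, they were 68 (10 cGy, 24 h minus 3 h), 38 (100 cGy, 24 h minus 3 h) and 0 (100 cGy, 72 h minus 24 h).

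A replicate block gave 51 (100 cGy, 24 h), 138 (100 cGy, 72 h), 128 (between doses, 24 h), 302 (10 cGy, 24 h minus 3 h) and 3664 (mock, 72 h against 1 h). Overlaps were 18 and 76 at 24 and 72 h, and the cause was not tested. Array weights gave 1271 and 298 (10 cGy, 3 and 24 h) and 5139, 4040 and 145 (100 cGy, 1, 3 and 72 h). They gave 296, 5384 and 120 (between doses, 1, 3 and 72 h) and 3512, 1041 and 0 (100 cGy, 3 h minus 1 h, 24 h minus 3 h and 72 h minus 24 h). Overlaps were 470 and 17 at 3 and 24 h, and the cause was not tested. Without replicates 2 and 3 of 100 cGy at 3 h, where the lone library is assumed to vary like the other groups, the counts were 117 (100 cGy, 3 h), 33 (between doses, 3 h), 1062 (3 h minus 1 h) and 28 (24 h minus 3 h).

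Without 1 library, counts for 10 cGy ran from 3485 to 4185 at 1 h, 19 to 664 at 3 h, 110 to 753 at 24 h and 500 to 1848 at 72 h. Those for 100 cGy ran from 2402 to 2770, 529 to 3544, 1 to 80 and 2 to 751. Between doses they ran from 70 to 121, 427 to 4342, 6 to 256 and 0 to 399. Differences between successive times ran from 2156 to 2615, 124 to 674 and 0 to 41 for 10 cGy and from 1486 to 2728, 143 to 1447 and 0 to 60 for 100 cGy. Mock times ran from 7245 to 7883, 6039 to 6654 and 5051 to 5738, and overlaps from 1957 to 2561, 13 to 288, 1 to 43 and 2 to 351. The cause was not tested.

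Of 152 list tests 63 were called, against 2 with an estimated correlation, 39 with fry and 61 on rescaling. The jasmonate list turned round at 24 h without 10 cGy replicate 1 (adjusted p = 0.000647 against 0.921) and without 100 cGy replicate 1 (0.0465 against 0.442). Without 1 library these p-values ran from 0.000647 to 0.791 and from 0.000113 to 0.822, and the cause was not tested.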

Other observations

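All groups and tests in this part were chosen after the data were seen. Values with an estimated correlation come from camera on the fold changes. Fisher's test compares shares of called genes and treats genes as independent, so the 2 are different tests. At 72 h after 10 cGy ribosomal protein genes fell, 181 of 310 measured (202 after rescaling by median ratios), as the L4/L1 family gene AT5G02870 by -0.37 (SE 0.06, adjusted p = 0.000767 by limma). The share exceeded that of other genes (Fisher adjusted p = 3.03e-159), and camera gave adjusted p = 0.324 with an estimated correlation. The number was 180, 43 or 194 without mock replicate 1, 2 or 3 and 100, 117 or 168 without 10 cGy replicate 1, 2 or 3. In the same comparison 46 of 141 genes for NLR immune receptors, which detect pathogen effectors, rose (43 after rescaling), as RPS4 by 0.43 (SE 0.06, adjusted p = 0.000534 by limma). Their Fisher adjusted p was 4.74e-24, and camera gave adjusted p = 0.324 with an estimated correlation. The number was 35, 19 or 45 without mock replicate 1, 2 or 3 and 26, 25 or 33 without 10 cGy replicate 1, 2 or 3.

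Cytochrome P450 genes fell at 1 h, 38 of 135 after 10 cGy (Fisher adjusted p = 8.78e-06, and adjusted p = 0.685 with an estimated correlation) and 38 after 100 cGy (4.2e-11, and adjusted p = 0.608 with an estimated correlation). Aquaporin genes, for water channels, fell in 11 of 23 cases at 1 h after 10 cGy (0.00071, and adjusted p = 0.378 with an estimated correlation) and 8 of 23 at 3 h after 100 cGy (3.6e-07, and adjusted p = 0.324 with an estimated correlation). Arabinogalactan protein genes, of the cell surface, fell in 11 of 36 cases at 3 h after 100 cGy (3.35e-09, and adjusted p = 0.188 with an estimated correlation).

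Principal components 1 to 5 of the 36 libraries held 33.4%, 21.1%, 12.8%, 6.4% and 3.2% of the variance. The 100 cGy 72 h replicate 3 lay at 25.3 on component 3, against -16.1 and -7.45 for replicates 1 and 2. Chloroplast genes held 0.153% to 0.608% of a library, the highest share being that of 10 cGy 3 h replicate 1 and the next 0.331%.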
